A study of Mus musculus with 10 samples.

How the data were processed

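Poly-A RNA of the mouse osteosarcoma cell line K7M2 and of 4 derived lines was sequenced on a DNBSEQ platform after dUTP strand-marked library preparation, per the labels' protocols. Per the labels, the 10 libraries form 5 groups of 2: parental cells, and ezrin-disrupted cells with an empty vector, wild-type ezrin, ezrin T567A or ezrin T567D. The authors deposited 1 table of raw counts per gene name and 1 table of RPKM values for each library, over 41743 gene names. The deposited counts are whole numbers with a different total in each library. The RPKM values in the deposited tables equal the count divided by a gene length and by a read total that is not the sum of the count table. The reads were aligned to GRCm38, per the submitters' processing notes. The aligner, the counting tool, the annotation release and whether counting used the strand are not given in the sources used here, so genes that overlap or lie antisense to another, and near-identical copies, have uncertain counts. Of the gene names, 173 are numbered copies of another name.

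Groups and replicate numbers were taken from the sample labels. No 2 files held identical counts. The chi-square of the counts of the 2 libraries of a line, per degree of freedom, was 4.19 in parental, 3.16 in empty-vector, 2.44 in wild-type, 8.45 in T567A and 4.35 in T567D libraries, above sampling noise in each. Total counts were 17715944 and 17570903 in parental, 17669729 and 17227902 in empty-vector, 16846966 and 17157736 in wild-type, 14679424 and 18230763 in T567A and 17079467 and 16790455 in T567D libraries. At these depths 3 counts in a library, used as the floor, equal 0.165 to 0.204 CPM.

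Counts were tested with edgeR 4.0.16 in R 4.3.3: genes were kept by filterByExpr (minimum count 10, minimum total 15), which left 12595, libraries were scaled by TMM, and all 10 libraries entered 1 robust quasi-likelihood fit with 5 group means and 5 residual degrees of freedom. A gene was called at a two-sided Benjamini-Hochberg adjusted p under 0.05, and log2 fold changes are the first line minus the second. The 5 main comparisons were empty vector minus parental, wild type minus empty vector, T567A minus wild type, T567D minus wild type and T567A minus T567D. There were 3 secondary ones: T567A and T567D each minus empty vector, and wild type minus parental. Where a group had 0 counts the fold was computed against the floor and is a lower bound, and with 1 to 3 counts the ratio is given with an exact 95% binomial interval. Floors and intervals cover counting error only.

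The design, the alternatives, the rule for named genes and 32 gene lists were fixed before the data were examined. Lists with at least 5 tested genes were compared with all other genes by camera in limma 3.58.1, on voom log2 CPM with a preset inter-gene correlation of 0.01, and again with an estimated correlation, with Benjamini-Hochberg adjustment over the lists of a comparison. Of all calls of list tests in the 8 comparisons, 66 with the preset correlation, 3 held with an estimated one, each for the interferon list. The named genes were Ezr, Msn and Rdx and, in each main comparison, the 8 called genes with the largest increase and the 8 with the largest decrease, among annotated genes that are neither pseudogenes nor unnamed models, with a mean of at least 10 CPM in the higher line and no overlap between the libraries of the 2 lines. In secondary comparisons the rule took 3 and 3. Up to 4 called members with at least 1 CPM were added for each list that passed camera or had at least 25% of its tested members called. Gene positions come from GENCODE M21, an annotation of GRCm38, matched by symbol for 40495 of the 41743 names and for 12422 of the 12595 tested genes. The codon of T567 was located from its ezrin coding sequence.

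Relations between derived lines were measured as correlations and covariances of log2 fold changes, with 20 simulations of unchanged lines for pairs that share the empty-vector libraries. These pairs were also measured with each empty-vector library in 1 of the 2 changes only. The alternatives were RLE and upper-quartile scaling, DESeq2 1.42.0, no filter or a filter of 5 CPM in 2 libraries, the replicate number as a block, only the libraries of the 2 lines compared, a test against a 1.5-fold change, an adjusted p under 0.01, limma on log2(RPKM + 1) and log2(RPKM + 0.1) of the deposited RPKM values, and leaving out each library in turn. The test was checked on simulated counts of the 12595 genes: for T567A minus wild type it recovered 68% of genes changed 1.5-fold and 88% of those changed 2-fold, with 13 false calls among 169, and for T567D minus wild type 77% and 86%, with 14 among 177. Moving the interferon list 1.3-fold in simulated T567A counts gave a call for that list and for no other of 27. Genes were simulated independently of each other, so this check does not cover lists whose genes vary together. Figures were drawn with matplotlib 3.10.9. No comparison was made of protein, phosphorylation or RNA bound by ezrin, which counts per gene do not measure.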

Results

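Poly-A RNA sequencing measured gene expression in K7M2, a mouse osteosarcoma cell line, and in 4 lines derived from it after CRISPR/Cas9 disruption of the ezrin gene. Ezrin links actin filaments to the plasma membrane, and phosphorylation of its threonine T567 favours the open form that makes this link. The derived lines stably carried an empty vector, wild-type ezrin, ezrin T567A, which cannot be phosphorylated at that residue, or ezrin T567D, which mimics the phosphorylated residue. There were 5 groups of 2 libraries, called here the parental, empty-vector, wild-type, T567A and T567D lines. The titles of the 4 derived lines share 1 tag, read here as the name of 1 disrupted clone. A difference from parental cells that all these lines share may then be a single event of that clone. Total counts per library lay between 14679424, in T567A replicate 2, and 18230763, in T567A replicate 3. Mitochondrially encoded genes took 1.9% and 1.44% of the counts in the T567A libraries and between 0.844% and 1.33% in the other 8. Levels are given in CPM, which are counts scaled by the TMM-adjusted library total, as mean ± SD, n = 2 libraries, changes as log2 fold change ± standard error (SE), and positions on GRCm38. The labels do not say that the 2 libraries of a line came from separate cultures, so p-values measure only the spread between these libraries, which may be technical. Each construct was present in 1 stable line, so that effects of the construct and of the line could not be separated.

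Among the libraries, parental cells stood apart on the first principal component, which held 57.9% of the variance of log2 CPM. On the second, with 19.6%, T567A stood apart from the other derived lines. The third component, with 8.4%, separated the empty-vector line from the wild-type and T567D lines. Correlations across genes, which are not independent replicates, were lowest between parental and T567A libraries, at 0.935 to 0.941. They were highest, among pairs of different lines, between wild-type and T567D libraries, at 0.992 to 0.993.

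Ezr, the targeted gene, lies on the minus strand of chromosome 17, 6738041 to 6782784. The codon of T567, the threonine codon ACG, lies in exon 13 of 13 at 6739363 to 6739365. The Ezr level was 164.1 and 165.7 CPM in the parental libraries, 72.4 and 72.88 in the empty-vector libraries, 230.4 and 233.5 in the wild-type libraries, 247.7 and 252.8 in the T567A libraries, and 204 and 181.5 in the T567D libraries. Ezr mRNA was lower in the empty-vector line than in parental cells (log2 fold change -1.18 ± 0.066, adjusted p = 2.1e-12), by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. It was higher in the wild-type line than in the empty-vector line (1.67 ± 0.066, adjusted p = 2e-13). The T567A and wild-type lines differed in Ezr by 0.11 ± 0.062, which did not pass the test (adjusted p = 0.17). Ezr in T567D was -0.27 ± 0.062 relative to wild type (adjusted p = 0.032). This call was lost without wild-type replicate 1, wild-type replicate 3 or T567D replicate 3 (adjusted p of 0.2, 0.33 and 0.38). Counts per gene do not separate vector-derived from endogenous Ezr mRNA and show neither the edit nor residue T567. Of the related ERM genes, Msn, which encodes moesin, was at 654 ± 17 CPM in parental cells, 528 ± 2.1 in the empty-vector line, 527 ± 10 in wild type, 380 ± 7.1 in T567A and 658 ± 23 in T567D. Rdx, which encodes radixin, was at 330 ± 19 CPM in parental cells and between 220 ± 1.6 and 246 ± 5 in the derived lines.

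**Figure D1:**
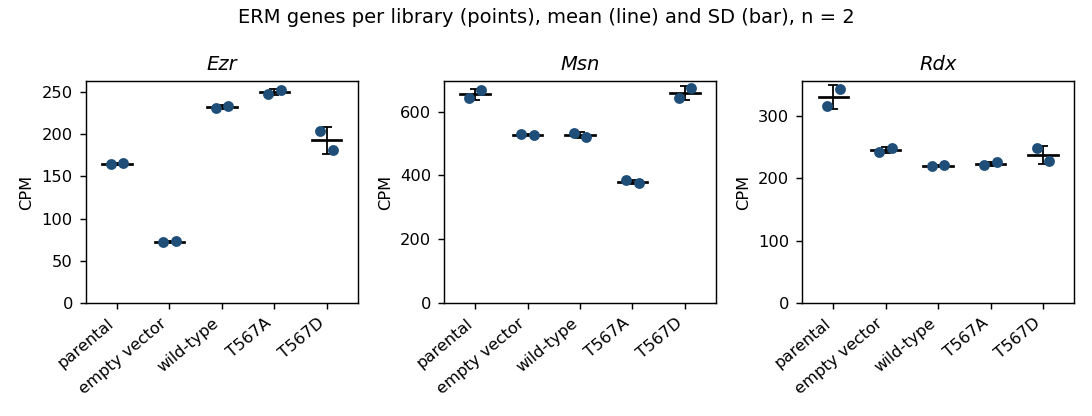
CPM of Ezr, Msn and Rdx in each of the 10 libraries (points), with the mean (line) and SD (bar) of the 2 libraries of each line. Ezr is lowest in the empty-vector line, at 72.6 CPM, and Msn is lowest in the T567A line, at 380 CPM.

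The comparison of the empty-vector line with parental cells asked how ezrin-disrupted cells differ from unedited ones, with disruption, derivation and stable transfection changing together. Mmp2, a gelatinase gene (chromosome 8, 92827291 to 92853420), fell from 119 ± 2.3 CPM to 1 count in the empty-vector libraries, a ratio of 4150 (counting interval 744 to 164000). Nsd1, which encodes a histone methyltransferase (chromosome 13, 55209782 to 55318325), fell from 23.6 ± 2.7 CPM to 0 counts, at least 138-fold lower. Ass1, an enzyme of arginine synthesis, fell to 3.34 ± 0.55 CPM against 244 ± 17 (log2 fold change -6.19 ± 0.11, adjusted p = 1.1e-20). Col1a1, the main collagen of bone (chromosome 11, 94936224 to 94953042), fell to 324 ± 4.7 CPM against 1820 ± 16 (-2.49 ± 0.072, adjusted p = 4.5e-17). In the other direction, Ccn3, a matricellular protein gene, rose to 52.6 ± 1.5 CPM against 1.89 ± 0.29 (4.79 ± 0.14). Cdc20b was at 33.9 ± 0.094 CPM in the empty-vector line against 0 counts in parental cells, at least 194-fold higher. The neutrophil chemokine genes Cxcl5 (150 ± 3.1 CPM against 21.5 ± 2.8, log2 fold change 2.80) and Cxcl1 (126 ± 3.4 CPM against 29.3 ± 0.16, 2.11) also rose.

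By group, the cytokine and chemokine list had 14 higher, 5 lower and 4 not called of 23 (14 and 5 adjusted over the list alone). The MAPK output list had 16 higher, 3 lower and 9 not called of 28 (17 and 4 adjusted over the list alone), with Etv1 (1.39), Fosl2 (1.15) and Etv5 (1.07) higher. Among matrix proteases and their inhibitors the counts were 13 higher, 8 lower and 1 not called of 22 (13 and 8 adjusted over the list alone), with Mmp3 (2.48) and Mmp9 (2.09) higher and Mmp2 lower. The protease list's median was 0.65, and its mean was -0.08. The NRF2 list had 16 higher, 6 lower and 6 not called of 28 (16 and 6 adjusted over the list alone), including the detoxification genes Nqo1 (140 ± 5.7 CPM against 48.1 ± 3.3, 1.54) and Hmox1 (176 ± 2.9 CPM against 67.3 ± 0.19, 1.38). Class I antigen presentation had 5 higher, 14 lower and 2 not called of 21 (5 and 14 adjusted over the list alone), with the transactivator Nlrc5 at -0.94. Extracellular matrix genes went both ways, with 10 higher, 12 lower and 4 not called of 26 (10 and 12 adjusted over the list alone), a median of -0.26 and a mean of 0.13. The same held for osteoblast differentiation genes, with 6 higher, 7 lower and 1 not called of 14 (6 and 8 adjusted over the list alone). Integrins and cadherins had 12 higher, 4 lower and 5 not called of 21 (12 and 4 adjusted over the list alone), with Pcdh7 at 4.42 and Itga11 at -5.21. RNA-binding protein genes had 6 higher, 16 lower and 18 not called of 40 (6 and 16 adjusted over the list alone). Cell cycle genes had 5 higher, 16 lower and 12 not called of 33 (7 and 16 adjusted over the list alone). ERM genes and partners had 5 higher, 7 lower and 6 not called of 18 (5 and 7 adjusted over the list alone).

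Of 12595 tested genes, 6879 were called at an adjusted p under 0.05, 3448 higher and 3431 lower (edgeR's quasi-likelihood test, Benjamini-Hochberg adjustment). Of these, 1663 differed over 2-fold. No list passed the camera test, the smallest adjusted p being 0.066 for both the MAPK and NRF2 lists (0.64 with an estimated correlation). Without 1 library the count lay between 5638 and 5919. The larger side turned under 8 of 16 other settings, with 48.3% to 56% of calls higher. The wild-type line compared with parental cells gave 7084 calls, 3489 higher and 3595 lower, a majority that turned under 8 of 16 other settings (48.2% to 56.9% higher). In that comparison the translation factor, cell cycle, class I, cholesterol and MAPK lists passed camera with the preset correlation. None of these held with an estimated correlation (camera adjusted p = 0.57 for each). Over 2-fold there, 993 were higher and 642 lower. Among them were Mmp2 at -8.96, the sialic acid pathway gene Renbp at -7.63 and Cftr at 5.61. There Nsd1 was at 3 counts, a ratio of 273 (counting interval 93.1 to 1330).

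The comparison of the wild-type line with the empty-vector line asked what restored ezrin changes in disrupted cells. Enzymes of cholesterol biosynthesis fell together: 0 of 25 tested genes were higher, 22 were lower and 3 were not called (0 higher and 22 lower adjusted over the list alone), with a median of -0.45. The cholesterol list gave camera adjusted p = 2.5e-19, and adjusted p = 0.079 with an estimated correlation. Hmgcs1, which encodes an early enzyme of the pathway, fell to 78.9 ± 2 CPM against 141 ± 2 (-0.83 ± 0.067, adjusted p = 2.6e-08). Fdps was at -0.69. In parental cells Hmgcs1 (114 ± 8.8 CPM) and Fdps (234 ± 8.6 CPM) lay above their wild-type levels. Cyp51 lay below its own, at 94.8 ± 7.2 CPM in parental cells against 145 ± 8.3 in wild type. The fall was thus not in each gene a return to the parental level. The chemokine gene Cxcl5 fell to 32 ± 0.17 CPM against 150 ± 3.1 (-2.23 ± 0.089, adjusted p = 2.8e-13) and Cxcl1 to 47.5 ± 0.64 CPM against 126 ± 3.4 (-1.41). Trpm6, a magnesium channel gene (chromosome 19, 18749983 to 18892511), rose to 19.1 ± 0.78 CPM against 3.98 ± 0.75 (2.26 ± 0.15, adjusted p = 1.3e-09).

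Cell cycle genes were lower in the wild-type line, where 0 of 33 tested genes were higher, 20 were lower and 13 were not called (0 higher and 21 lower adjusted over the list alone), including Ccnb1 (204 ± 6.6 CPM against 299 ± 2.6, -0.55) and Aurka (-0.31). The cell cycle list gave camera adjusted p = 1.3e-08, and adjusted p = 0.2 with an estimated correlation. For class I antigen presentation 0 of 21 tested genes were higher, 10 were lower and 11 were not called (0 higher and 11 lower adjusted over the list alone), with the immunoproteasome gene Psmb8 at -0.85. The class I list gave camera adjusted p = 4.8e-05, and adjusted p = 0.2 with an estimated correlation. Both the cell cycle and class I lists already had more members lower than higher in the empty-vector line against parental cells. Cytokines and chemokines had 0 higher, 8 lower and 15 not called of 23 (1 and 8 adjusted over the list alone), Cxcl5 and Cxcl1 among them. The cytokine list gave camera adjusted p = 0.0015, and adjusted p = 0.2 with an estimated correlation. Extracellular matrix genes had 7 higher, 2 lower and 17 not called of 26 (8 and 2 adjusted over the list alone), with Lox, which cross-links collagen, at -0.58 and a median of 0.30. The matrix list gave camera adjusted p = 0.0013, and adjusted p = 0.29 with an estimated correlation. Among ERM genes and partners 6 of 18 tested genes were higher, 0 were lower and 12 were not called (6 higher and 0 lower adjusted over the list alone), Ezr and Podxl included. Ezr, which the wild-type vector was built to supply, is 1 of the 6. It stayed in the list test, so that test does not measure the partners alone. Podxl, a sialomucin gene, was at 9.63 ± 0.37 CPM against 3.26 ± 0.35 (1.56 ± 0.16). The ERM list's camera adjusted p of 0.029 became 0.053 without empty-vector replicate 2, and was 0.2 with an estimated correlation. Osteoblast differentiation genes had 6 higher, 3 lower and 5 not called of 14 (7 and 3 adjusted over the list alone), with Omd at 1.26. Their camera call (adjusted p = 0.046) was lost without each of 6 libraries (0.055 to 0.084) and with an estimated correlation (adjusted p = 0.2). Mitochondrially encoded genes had a median of 0.44 with 0 of 13 called by edgeR. The mitochondrial list gave camera adjusted p = 6.5e-05, and adjusted p = 0.45 with an estimated correlation. At an unadjusted p under 0.05, 1 of the 13 passed by edgeR and 4 by DESeq2, which also called 0 after adjustment, as did limma. Integrated stress response genes had 3 higher, 9 lower and 17 not called of 29 (3 and 10 adjusted over the list alone). The stress response list gave camera adjusted p = 0.017, and adjusted p = 0.48 with an estimated correlation, a call lost without wild-type replicate 3 (adjusted p = 0.068). Wnt signalling genes had 2 higher, 1 lower and 10 not called of 13 (2 and 1 adjusted over the list alone). The Wnt list gave camera adjusted p = 0.034, and adjusted p = 0.2 with an estimated correlation, a call lost without empty-vector replicate 2 (adjusted p = 0.076) or wild-type replicate 1 (0.052). Replication-dependent histone genes, whose mRNA mostly lacks poly-A tails, had 3 higher, 0 lower and 3 not called of 6 (3 and 0 adjusted over the list alone). The histone list gave camera adjusted p = 0.021, and adjusted p = 0.2 with an estimated correlation, a call lost without each of 4 libraries (0.052 to 0.062). The surface genes Itgb3 (2.28), Itga11 (2.06) and Anpep (1.37) and the contractile gene Acta2 (44.9 ± 4.4 CPM against 22.3 ± 1.9, 1.01) were higher. Cdc20b was at 0 counts in the wild-type line, at least 196-fold lower.

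In this comparison 1966 genes were called, 1039 higher and 927 lower, and 221 differed over 2-fold, 190 of them higher. With upper-quartile scaling the split was 1249 higher and 674 lower. The count was 853 without empty-vector replicate 2, 1020 without empty-vector replicate 3, 871 without wild-type replicate 1 and 995 without wild-type replicate 3.

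The comparison of the T567A line with the wild-type line asked what the nonphosphorylatable residue changes. Interferon-response genes rose together in T567A: 39 of 41 tested genes were higher, 0 were lower and 2 were not called (40 higher and 0 lower adjusted over the list alone), with a median of 1.22. The interferon list gave camera adjusted p = 1.6e-41, and adjusted p = 0.013 with an estimated correlation. The antiviral gene Rsad2 (chromosome 12, 26442746 to 26456452) rose to 113 ± 10 CPM against 19.5 ± 1.1 (2.53 ± 0.092, adjusted p = 1.2e-14) and Ifit1 to 772 ± 4.9 CPM against 200 ± 4 (1.95 ± 0.058). The lymphocyte chemokine gene Cxcl10 rose to 320 ± 3.7 CPM against 72 ± 4 (2.15 ± 0.064, adjusted p = 6.7e-16). Of the class I antigen presentation list 19 of 21 tested genes were higher, 0 were lower and 2 were not called (19 higher and 0 lower adjusted over the list alone). The peptide transporter gene Tap1 was at 217 ± 12 CPM against 85.3 ± 0.88 (1.35), Nlrc5 at 1.35 and H2-T22 at 1.20. The class I list gave camera adjusted p = 1.6e-15, and adjusted p = 0.055 with an estimated correlation. Reads of H2-T22 and other class I genes can be shared with near-identical copies, so that the level of each single gene is uncertain. Cholesterol enzymes, lower in wild type than in the empty-vector line, were higher in T567A than in wild type: 23 of 25 tested genes were higher, 0 were lower and 2 were not called (24 higher and 0 lower adjusted over the list alone). Cyp51 was at 321 ± 3.1 CPM against 145 ± 8.3 (1.14 ± 0.065, adjusted p = 1.2e-11), Idi1 at 1.15 and Msmo1 at 1.10. The cholesterol list gave camera adjusted p = 4e-17, and adjusted p = 0.054 with an estimated correlation.

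Among genes lower in T567A, Egln3, an oxygen-sensing hydroxylase gene (chromosome 12, 54178981 to 54203860), fell to 2.02 ± 0.22 CPM against 15.5 ± 0.69 (-2.93 ± 0.16, adjusted p = 5.1e-12). Fn1, which encodes fibronectin, fell to 50.6 ± 1 CPM against 168 ± 7.4 (-1.73 ± 0.098, adjusted p = 8.4e-10). Extracellular matrix genes had 3 higher, 13 lower and 10 not called of 26 (4 and 17 adjusted over the list alone), with Col6a2 (-1.93), Tnc (-1.80) and Fbln5 (-1.64) lower. The matrix list gave camera adjusted p = 0.00014, and adjusted p = 0.26 with an estimated correlation. Col1a1, on the osteoblast list, went the other way, to 603 ± 7.9 CPM against 259 ± 18 (1.22 ± 0.07), as did Omd (1.87). The osteoblast list had 6 higher, 2 lower and 6 not called of 14 (7 and 2 adjusted over the list alone). That list gave camera adjusted p = 0.012, and adjusted p = 0.2 with an estimated correlation. MAPK output genes had 2 higher, 13 lower and 13 not called of 28 (2 and 14 adjusted over the list alone), with Etv4 (-1.09) and Dusp4 (-1.05) lower. The MAPK list gave camera adjusted p = 0.00035, and adjusted p = 0.26 with an estimated correlation. Cell cycle genes had 0 higher, 16 lower and 17 not called of 33 (0 and 17 adjusted over the list alone), with Cenpa (-0.61), Cdc20 (-0.53) and Foxm1 (-0.43) lower. The cell cycle list gave camera adjusted p = 8.9e-05, and adjusted p = 0.37 with an estimated correlation. Actin cytoskeleton genes had 3 higher, 11 lower and 7 not called of 21 (3 and 12 adjusted over the list alone), with Pdlim7 at -0.74. The actin list gave camera adjusted p = 0.029, and adjusted p = 0.43 with an estimated correlation, a camera call lost without wild-type replicate 1 (adjusted p = 0.1). ERM genes and partners had 1 higher, 7 lower and 10 not called of 18 (1 and 7 adjusted over the list alone), with Msn at -0.47 (adjusted p = 1.2e-06) and Pdpn, which encodes podoplanin, at -1.17. This list did not pass camera (adjusted p = 0.11).

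Glycolysis and hypoxia genes had 15 higher, 1 lower and 12 not called of 28 (15 and 1 adjusted over the list alone), with Pdk1 (0.85) and Bnip3 (0.81) higher and Egln3 the 1 lower member. The glycolysis and hypoxia list gave camera adjusted p = 0.00025, and adjusted p = 0.2 with an estimated correlation. The cytokine list had 12 higher, 4 lower and 7 not called of 23 (13 and 4 adjusted over the list alone), with the chemokine genes Ccl5 (171 ± 22 CPM against 47.1 ± 0.66, 1.86) and Ccl7 (1.32) higher. Cytokine genes gave camera adjusted p = 0.0011, and adjusted p = 0.2 with an estimated correlation. Ccl5 is also on the interferon list. Integrated stress response genes had 14 higher, 4 lower and 11 not called of 29 (16 and 5 adjusted over the list alone), with Trib3 (0.87) and Atf4 (0.59) higher. The stress response list gave camera adjusted p = 0.0012, and adjusted p = 0.38 with an estimated correlation. RNA-binding protein genes had 10 higher, 7 lower and 23 not called of 40 (10 and 7 adjusted over the list alone) and did not pass camera (adjusted p = 0.29). These groups moved beside the mitochondrial share of 1.9% and 1.44% in T567A against 1.21% and 1.33% in wild type, and beside the lowest total count, 14679424, in T567A replicate 2. Mitochondrially encoded genes had a median of 0.45, with mt-Co3 called (0.63) and 12 not called. The mitochondrial list gave camera adjusted p = 0.008, and adjusted p = 0.51 with an estimated correlation, a camera call lost without T567A replicate 2 (adjusted p = 0.18). Oxidative phosphorylation genes had 10 higher, 1 lower and 23 not called of 34 (10 and 1 adjusted over the list alone) and a median of 0.07. The oxidative phosphorylation list gave camera adjusted p = 0.047, and adjusted p = 0.51 with an estimated correlation, a call lost without each of 6 libraries (0.051 to 0.24) and with RLE scaling (0.057). Outside the lists, the small proteoglycan gene Ogn rose to 528 ± 20 CPM against 123 ± 2.3 (2.10 ± 0.068).

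In T567A against wild type 4983 genes were called, 2574 higher and 2409 lower, and 642 differed over 2-fold. Which side was larger turned under 10 of 16 other settings. The share higher lay between 43.8%, with upper-quartile scaling (2186 higher and 2802 lower), and 60%, against a 1.5-fold change (295 and 197). The count was 3314 without wild-type replicate 1.

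**Figure D2:**
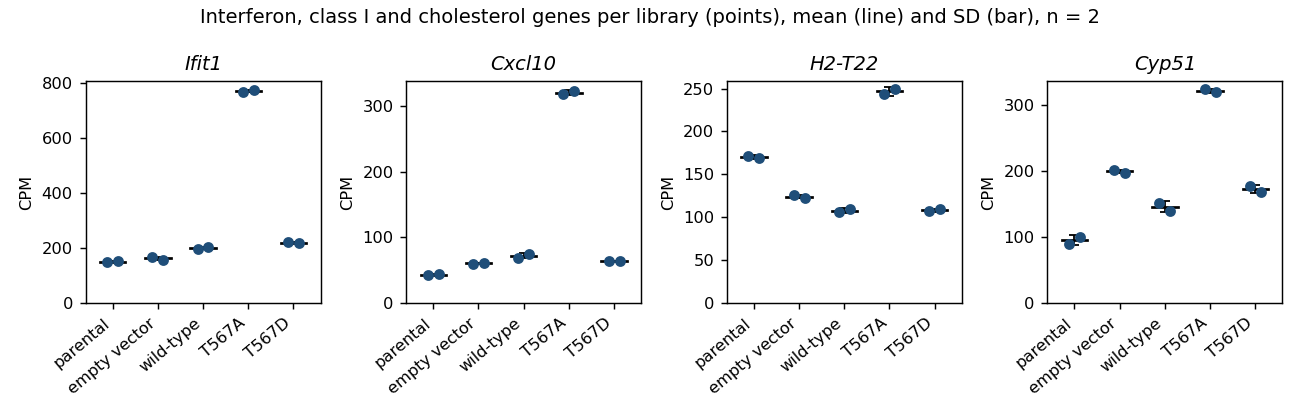
CPM of Ifit1, Cxcl10, H2-T22 and Cyp51 in each of the 10 libraries (points), with the mean (line) and SD (bar) of the 2 libraries of each line. All 4 genes are highest in the T567A line, Ifit1 at 772 CPM against 200 in the wild-type line.

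The comparison of the T567D line with the wild-type line asked what the phosphomimetic residue changes. Col1a1 rose to 735 ± 84 CPM against 259 ± 18 (1.5 ± 0.07, adjusted p = 1.4e-11) and Fn1 to 265 ± 3.4 CPM against 168 ± 7.4 (0.66 ± 0.089, adjusted p = 0.00087). Sulf2, a heparan sulfate sulfatase gene, rose to 25.2 ± 1.8 CPM against 13 ± 0.58 (0.96 ± 0.096), and the matrix proteoglycan gene Prelp was at 0.86 (adjusted p = 2.8e-05). The actin-binding genes Cotl1 (20.1 ± 0.29 CPM against 10.5 ± 0.72, 0.94) and Lcp1 (0.81) were higher. Trpm6 fell to 5.61 ± 1.1 CPM against 19.1 ± 0.78 (-1.77 ± 0.14, adjusted p = 1.5e-07), and Hopx (-1.01) and Plce1 (-0.85) were also lower. Egln3 was at 0.68 and Mmp9 at 0.48. Most named genes called in this comparison lost their call under some of the settings given below.

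Few list members were called. Cholesterol genes had 1 higher, 0 lower and 24 not called of 25 (9 and 0 adjusted over the list alone) and a median of 0.13. The cholesterol list gave camera adjusted p = 4.3e-08, and adjusted p = 0.47 with an estimated correlation. Actin cytoskeleton genes had 3 higher, 0 lower and 18 not called of 21 (4 and 0 adjusted over the list alone), the called ones being Flna (0.37), Cnn2 (0.32) and Acta2 (0.40), with a median of 0.12. The actin list gave camera adjusted p = 1.6e-05, and adjusted p = 0.47 with an estimated correlation. All 3 calls were lost without wild-type replicate 3, at adjusted p of 0.1, 0.21 and 0.36. Those of Cnn2 and Acta2 were also lost without T567D replicate 3 (0.064 and 0.095), and that of Acta2 without T567D replicate 1 (0.086). Extracellular matrix genes had 3 higher, 1 lower and 22 not called of 26 (5 and 1 adjusted over the list alone). The matrix list gave camera adjusted p = 0.012, and adjusted p = 0.52 with an estimated correlation. That camera call was lost without wild-type replicate 3 (adjusted p = 0.092) or T567D replicate 3 (0.095). Mitochondrially encoded genes had a median of -0.23 with 0 of 13 called. Their list gave camera adjusted p = 0.03, and adjusted p = 0.75 with an estimated correlation. That downward call was lost without wild-type replicate 3 (adjusted p = 0.42) or T567D replicate 1 (0.66). Oxidative phosphorylation genes had 0 higher, 0 lower and 34 not called of 34 (0 and 0 adjusted over the list alone) and a median of 0.04. The oxidative phosphorylation list gave camera adjusted p = 0.03, and adjusted p = 0.68 with an estimated correlation, a call lost without wild-type replicate 1 (adjusted p = 0.18) or T567D replicate 1 (0.21). Glycolysis and hypoxia genes had 1 higher, 0 lower and 27 not called of 28 (1 and 0 adjusted over the list alone) and a median of -0.11. The glycolysis and hypoxia list gave camera adjusted p = 0.047, and adjusted p = 0.52 with an estimated correlation, a downward call lost without each of 6 libraries (0.06 to 0.18). Msn was higher at 0.32 ± 0.056 (adjusted p = 0.0036). The Msn call was lost without wild-type replicate 3 or T567D replicate 3 (adjusted p of 0.11 and 0.058). Interferon-response genes had 0 higher, 1 lower and 40 not called of 41 (0 and 2 adjusted over the list alone) and a median of -0.01 (camera adjusted p = 0.66). Class I genes had 0 higher, 0 lower and 21 not called of 21 (0 and 0 adjusted over the list alone). For RNA-binding proteins the counts were 0 higher, 0 lower and 40 not called of 40 (0 and 0 adjusted over the list alone). At an unadjusted p under 0.05, 4 of the 40 RNA-binding genes passed by edgeR and 2 by DESeq2. For the 21 class I genes the numbers were 0 and 1. Neither DESeq2 nor limma called any of them after adjustment.

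In T567D against wild type 169 genes were called, 103 higher and 66 lower, of which 21 differed over 2-fold. The count was 65 without wild-type replicate 1, 47 without wild-type replicate 3, 82 without T567D replicate 1 and 110, split evenly at 55 and 55, without T567D replicate 3.

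**Figure D3:**
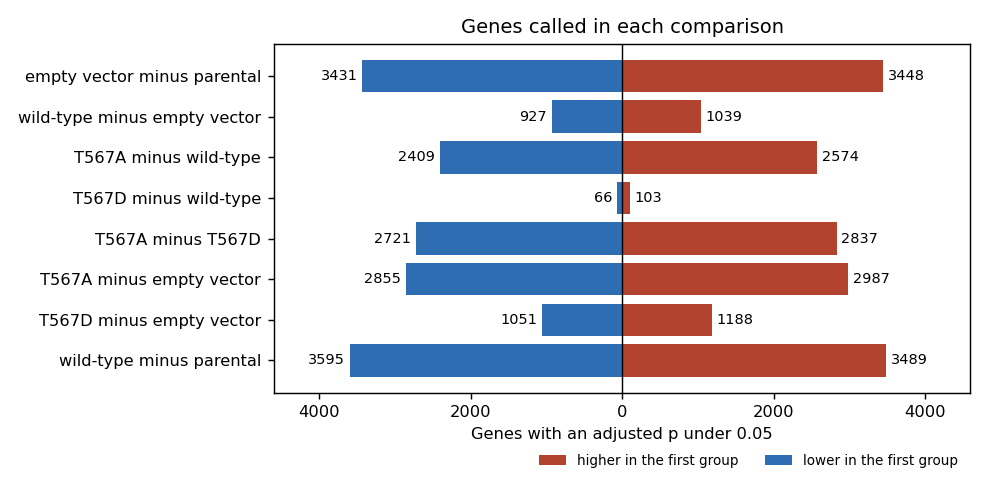
Numbers of genes with an adjusted p under 0.05 in each comparison (horizontal axis), higher (right) or lower (left) in the line named first, by edgeR's quasi-likelihood test. T567D against wild type has 169 calls, 103 higher and 66 lower, and T567A against wild type has 4983.

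The comparison of the T567A line with the T567D line set the forms of residue T567 against each other directly. Interferon genes were higher in T567A: 40 of 41 tested genes were higher, 0 were lower and 1 was not called (40 higher and 0 lower adjusted over the list alone). Rsad2 was at 113 ± 10 CPM against 14.8 ± 1.3 (2.93 ± 0.096, adjusted p = 1.8e-15) and Cxcl10 at 2.34. The interferon list gave camera adjusted p = 3.9e-38, and adjusted p = 0.015 with an estimated correlation. Class I genes had 20 higher, 0 lower and 1 not called of 21 (20 and 0 adjusted over the list alone). The class I list gave camera adjusted p = 3.5e-13, and adjusted p = 0.075 with an estimated correlation. Cholesterol genes had 21 higher, 0 lower and 4 not called of 25 (21 and 0 adjusted over the list alone), with Idi1 at 1.03 and Cyp51 at 0.90. The cholesterol list gave camera adjusted p = 2.5e-12, and adjusted p = 0.075 with an estimated correlation. Egln3 was lower in T567A, at 2.02 ± 0.22 CPM against 24.8 ± 0.66 (-3.60 ± 0.15, adjusted p = 7.4e-14). So were Fn1, at 50.6 ± 1 CPM against 265 ± 3.4 (-2.39 ± 0.098), and Pmepa1, a gene induced by TGF-beta, at 5.59 ± 0.2 CPM against 46.5 ± 12 (-3.05). Extracellular matrix genes had 3 higher, 15 lower and 8 not called of 26 (3 and 16 adjusted over the list alone). The matrix list gave camera adjusted p = 3.3e-05, and adjusted p = 0.25 with an estimated correlation.

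Actin cytoskeleton genes had 3 higher, 13 lower and 5 not called of 21 (3 and 13 adjusted over the list alone), with Tagln2 (-1.10), Pdlim7 (-0.97) and Flna (-0.80) lower in T567A. The actin list gave camera adjusted p = 0.00055, and adjusted p = 0.33 with an estimated correlation. MAPK output genes had 2 higher, 15 lower and 11 not called of 28 (2 and 15 adjusted over the list alone). The MAPK list gave camera adjusted p = 0.00083, and adjusted p = 0.32 with an estimated correlation. Cell cycle genes had 0 higher, 17 lower and 16 not called of 33 (0 and 18 adjusted over the list alone). The cell cycle list gave camera adjusted p = 5e-05, and adjusted p = 0.36 with an estimated correlation. Glycolysis and hypoxia genes had 18 higher, 2 lower and 8 not called of 28 (18 and 2 adjusted over the list alone). The glycolysis and hypoxia list gave camera adjusted p = 3e-05, and adjusted p = 0.18 with an estimated correlation. Cytokines and chemokines had 13 higher, 3 lower and 7 not called of 23 (13 and 3 adjusted over the list alone). The cytokine list gave camera adjusted p = 0.00083, and adjusted p = 0.24 with an estimated correlation. Integrated stress response genes had 16 higher, 6 lower and 7 not called of 29 (16 and 6 adjusted over the list alone), with Slc7a11 at 1.65. The stress response list gave camera adjusted p = 0.0034, and adjusted p = 0.44 with an estimated correlation. Among ERM genes and partners 5 of 18 tested genes were higher, 7 were lower and 6 were not called (6 higher and 7 lower adjusted over the list alone), with Msn at -0.79 (adjusted p = 4.1e-10) and Ezr at 0.38 (adjusted p = 5e-05). Mitochondrially encoded genes had 4 higher, 0 lower and 9 not called of 13 (1 and 0 adjusted over the list alone) and a median of 0.60. The mitochondrial list gave camera adjusted p = 0.00047, and adjusted p = 0.45 with an estimated correlation, beside mitochondrial shares of 1.9% and 1.44% in T567A and 1.01% and 1.24% in T567D. The test called 5558 genes, 2837 higher and 2721 lower in T567A, and 779 differed over 2-fold. Here the larger side turned under 9 of 16 other settings, with 44.5% to 52.5% of calls higher.

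**Figure D4:**
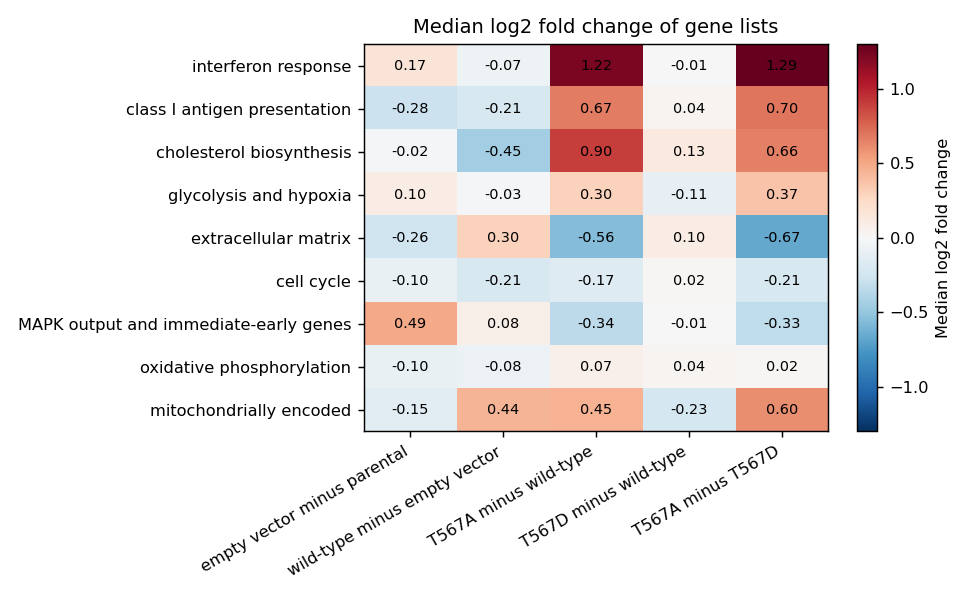
Median log2 fold change (color scale and printed values) of 9 gene lists (vertical axis) in the 5 main comparisons (horizontal axis). The interferon list stands at 1.22 in T567A minus wild type and at -0.01 in T567D minus wild type.

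Against the empty-vector line, T567A had 5842 calls, 2987 higher and 2855 lower, and T567D had 2239, 1188 higher and 1051 lower. Over 2-fold, 576 were higher and 303 lower in T567A, and 235 were higher and 30 lower in T567D. Tested against a 1.5-fold change, the calls were 531 higher and 277 lower in T567A and 86 and 14 in T567D. The larger side in T567A turned under 5 of 16 other settings, with 46.6% to 65.7% of calls higher. Interferon genes had 40 higher, 0 lower and 1 not called of 41 (40 and 0 adjusted over the list alone) in T567A. Those genes gave camera adjusted p = 1.3e-33, and adjusted p = 0.021 with an estimated correlation. In T567D they had 4 higher, 7 lower and 30 not called of 41 (6 and 11 adjusted over the list alone) (camera adjusted p = 0.23). Megf6 (5.25), Fmnl1 (3.74) and Ogn (3.33) were higher in T567A and Hspb7 (-2.83) and Adamts2 (-2.47) lower. In T567D, Lcp1 (1.96), Arhgef6 (1.75) and Egln3 (1.53) were higher and Cxcl5 (-2.44) and Map6 (-1.76) lower. Cholesterol genes had 16 higher, 0 lower and 9 not called of 25 (16 and 1 adjusted over the list alone) in T567A. The cholesterol list there gave camera adjusted p = 0.0002, and adjusted p = 0.34 with an estimated correlation. In T567D cholesterol genes had 0 higher, 16 lower and 9 not called of 25 (0 and 18 adjusted over the list alone). Cholesterol genes there gave camera adjusted p = 1.3e-09, and adjusted p = 0.17 with an estimated correlation. For the cell cycle list the counts were 0 higher, 26 lower and 7 not called of 33 (0 and 26 adjusted over the list alone) in T567A. Its test there gave camera adjusted p = 2.7e-10, and adjusted p = 0.27 with an estimated correlation. In T567D they were 0 higher, 14 lower and 19 not called of 33 (0 and 18 adjusted over the list alone). That test gave camera adjusted p = 2.1e-07, and adjusted p = 0.23 with an estimated correlation. These list changes stand beside higher mitochondrially encoded genes in T567A, with 11 higher, 0 lower and 2 not called of 13 (12 and 0 adjusted over the list alone) and a median of 0.83. The mitochondrial list there gave camera adjusted p = 1.1e-05, and adjusted p = 0.56 with an estimated correlation. In T567D, 0 of 13 were called and the median was 0.23. For T567D that list gave camera adjusted p = 0.019, and adjusted p = 0.56 with an estimated correlation. That call was lost without empty-vector replicate 3 (adjusted p = 0.35) or T567D replicate 3 (0.21). Other lists passed camera with the preset correlation but not with an estimated one. In T567A these were the osteoblast, glycolysis and hypoxia, class I and MAPK lists (camera adjusted p of 0.18 to 0.56 with an estimated correlation). In T567D they were the actin, matrix, osteoblast, glycolysis and hypoxia, class I, stress response, cytokine, Wnt and growth factor lists (0.17 to 0.41). With upper-quartile scaling the T567D split was 1375 higher and 795 lower. The T567D count was 1014 without empty-vector replicate 2, 1125 without empty-vector replicate 3, 1469 without T567D replicate 1 and 1120 without T567D replicate 3.

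How the 4 derived lines relate was measured across genes, which are not independent replicates, in 6 correlations of log2 fold changes. The 3 pairings without a shared library gave low values: 0.026 for wild type minus empty vector with T567A minus T567D, 0.033 for T567A minus wild type with empty vector minus T567D, and 0.079 for T567D minus wild type with empty vector minus T567A. Against the shared empty-vector libraries, the wild-type and T567D changes correlated at 0.784, where 20 simulations of unchanged lines averaged 0.497. Their covariance was 0.102 against a simulated 0.017, a difference of 0.085. Of their calls, 663 genes were higher in both, where independent lists would share 98, and 613 were lower in both, where independent lists would share 77. Another 2 went opposite ways. Here and below, both lists used the same empty-vector libraries, so the numbers for independent lists are not what unchanged lines would share. That overlap was not simulated. The T567A and T567D changes correlated at 0.459 (simulated 0.491), with a covariance of 0.0961 against a simulated 0.017. They shared 633 genes higher (282 for independent lists) and 560 lower (238), and 260 went in opposite directions. For wild type and T567A the correlation was 0.53 (simulated 0.5), with a covariance of 0.107 against a simulated 0.0175. Their calls shared 670 genes higher (246 for independent lists) and 580 lower (210), and 163 went in opposite directions. In a split chosen after these results were seen, each empty-vector library served 1 of the 2 changes, so that no library was shared. Correlations were then 0.566 and 0.597 for wild type with T567D, 0.336 and 0.366 for T567A with T567D, and 0.407 and 0.417 for wild type with T567A. The covariances, in the same order, were 0.0864 and 0.0893, 0.0783 and 0.0842, and 0.0913 and 0.0942. A trait of the single empty-vector line would enter both changes, and this stays open.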

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

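The comparisons behind these values were planned, and counting genes that moved in opposite directions was chosen after their results were seen. Against the same empty-vector libraries, 260 genes were called in opposite directions in T567A and T567D, 138 of them higher and 122 lower in T567A. All 260 were also called by the direct test of T567A minus T567D, which follows from how they were picked and adds no support. Among named genes the largest such differences, as T567A minus T567D log2 fold change, were Tnnt2 at -3.72, Egln3 at -3.60, Pmepa1 at -3.05 and Fabp4 at -2.90. Egln3 was -2.07 ± 0.17 in T567A and 1.53 ± 0.11 in T567D relative to the empty vector, and Pmepa1 was -2.03 ± 0.22 and 1.02 ± 0.16. Tnnt2 and Fabp4 had few counts in T567A, Tnnt2 at 0.228 ± 0.17 CPM (7 counts) in T567A and 2.94 ± 0.97 in T567D, and Fabp4 at 0.962 ± 0.49 and 6.97 ± 1.1. No explanation was tested for this set of genes.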

How the results depend on the processing

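Thinning every library to the smallest total, and the split of the empty-vector libraries between 2 changes, were chosen after the data were seen. Thinning left each count of called genes within 1.5 times. All other settings were planned. Among genes called both under a setting and as reported, the direction was the same in all 8 comparisons. The cause of the moves below was not tested, except that a higher bar for the fold or the adjusted p calls fewer genes by construction. Fewer libraries did not always call fewer genes. With only the 2 lines' libraries, wild type minus empty vector went from 1966 to 2955 calls. Where a line is left with 1 library, that library is assumed to vary like the other lines.

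For wild type minus empty vector the 1966 calls became 1226 by DESeq2, 2955 with only the 2 lines' libraries, 87 against a 1.5-fold change and 1000 at an adjusted p under 0.01, and lay between 853 and 1020 without 1 library. For T567D minus empty vector the 2239 became 1309 by DESeq2, 100 against a 1.5-fold change, 1087 at an adjusted p under 0.01, and 1014 to 1469 without 1 library. For T567D minus wild type the 169 became 300 with no low-count filter, 7 against a 1.5-fold change, 69 at an adjusted p under 0.01, 89 and 63 by limma on log2(RPKM + 1) and log2(RPKM + 0.1), and 47 to 110 without 1 library. Tested against a 1.5-fold change, 1857 genes were called in empty vector minus parental and 1857 in wild type minus parental, 492 in T567A minus wild type, 643 in T567A minus T567D and 808 in T567A minus empty vector. T567A minus wild type lay between 3314 and 5006 without 1 library. List tests past the threshold numbered 66, and 3 with an estimated correlation. The correlations of pairings without a shared library were 0.026, 0.033 and 0.079. They were 0.062, 0.057 and 0.181 over genes with at least 10 CPM, -0.014, 0.096 and 0.106 without the 500 most variable genes, and -0.013 to 0.047, -0.002 to 0.065 and 0.035 to 0.09 without 1 library.

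The replicate numbers did not pair the libraries: deviations of same-numbered libraries correlated at -0.0995 between wild type and T567D, -0.035 and -0.0469 between parental cells and these lines, and -0.0074 between empty vector and T567A. With the replicate number as a block, wild type minus empty vector had 1082 calls and T567D minus empty vector 1142. Single genes were not followed under thinning, the 1.5-fold bar or the adjusted p under 0.01. Over the remaining settings, the block included, named genes kept their side of the threshold in 6077 cases, lost it in 290, gained it in 1 and reversed in 0. Calls of gene lists were kept in 752 cases and lost in 106, 63 of these with an estimated correlation, and 64 were gained, 15 of them without T567A replicate 2. Among called named genes, 9 of 29 in T567D minus wild type and 97 of 112 in T567A minus wild type lost their call under none of the settings in which they were followed. For wild type minus empty vector this held for 54 of 81. At 2 libraries per line, the depth puts the floor at 0.165 to 0.204 CPM.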

Other observations

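The tests of stable-line differences, of depth by thinning, of parental cells and of shared empty-vector libraries were chosen after the results were seen, and the other 4 tests before. The test of shared libraries replaced an earlier one, a bound from simulated counts, which pointed the same way but could not exclude anything. Several genes outside the comparisons' main groups were close to all or none between lines, and their neighbours were looked up after their values were seen. Cdc20b (chromosome 13, 113035111 to 113091195) was at 33.9 ± 0.094 CPM in the empty-vector line, 0 counts in the parental, wild-type and T567A lines and 2 counts in T567D. Its neighbour Ccno was at 11.4 CPM in the empty-vector line and 2.44 to 4.74 in the others, while Gpx8, which lies within Cdc20b on the other strand, was at 110 CPM in both the parental and empty-vector lines. Whether counting used the strand is not known, so the counts of these overlapping genes are uncertain. Nsd1 was at 23.6 CPM in parental cells and at most 0.0867 in the 4 derived lines, a loss that may be a single event in a shared clone. Its neighbours Zfp346 (26.5 CPM in parental cells, 23 to 42 in the derived lines) and Rab24 (34 and 32.8 to 39) had no such drop. The median log2 fold change of empty vector minus parental was -0.77 over genes on the X chromosome and 0.44 over chromosome 13, and that of wild type minus parental was -0.69 and 0.30. In empty vector minus parental, chromosomes 3 (0.26) and 9 (-0.26) also had medians over 0.2 in size. These 4 chromosomes held 1530 of the 6797 calls with a position (22.5%). On X 324 of 373 genes were called, against 6797 of 12406 in all. Copy number was not tested for this comparison. In wild type minus empty vector the median was 0.21 over chromosome 19, which carries Trpm6 and 164 of that comparison's calls. It was 0.16 in T567A and 0.17 in T567D minus empty vector. Over chromosome 13 the medians were -0.13, -0.16 and -0.12 in wild type, T567A and T567D minus empty vector. Each ezrin line thus differed from the empty-vector line in the same direction on both chromosomes. Trpm6 did not follow this shift, being lower in T567D than in wild type. Of genes listed as markers of other cell types, several were expressed in each line on average: Csf1r, which encodes the receptor of a macrophage growth factor, at 1180 to 1620 CPM, Mmp9 at 40.9 to 287, Cd14 at 33 to 36.9 and Nfatc1 at 17.9 to 21. Ptprc was at no more than 0.409 CPM without TMM adjustment.

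Leukocytes in the T567A cultures are argued against as the source of the higher interferon genes, since the summed level of 6 leukocyte genes was 0.69 and 0.612 CPM in the T567A libraries, where Ifit1 was at 772 CPM against 200 in wild type. The sum differed by -1.11 CPM, T567A minus wild type, carried by Lyz2 (0.41 against 1.73 CPM). Of the macrophage and leukocyte list, Mpeg1 was called higher, at 10.7 ± 0.29 CPM against 3.57 ± 0.2, as was Csf1r, at a log2 fold change of 0.23. The shallower library is argued against too, since the list's median was 1.20 without T567A replicate 2 and 1.22 with it. The list's median varied by 0.08 over the empty-vector, wild-type and T567D lines, so that none of these lines moved as T567A did. With 1 line per construct, a difference of this stable line that arose apart from the mutation and an effect of residue T567 cannot be told apart. An effect of the nonphosphorylatable residue therefore may be the source, as a hypothesis that a second T567A line would test.

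The ratio of calls between T567A and T567D, each against wild type, was 29.5. It was 31.4 after thinning all libraries to 14679424 counts. Depth is argued against mainly by the close totals, the highest being 18230763. With such totals the ratio could hardly have moved by thinning. Over the other settings run for both comparisons it lay between 16.6, with no low-count filter, and 79.6, without wild-type replicate 3. Whole-chromosome copy number is argued against by the 0% of T567A calls on chromosomes with a median over 0.2 in size, the chromosome medians lying between -0.09 and 0.11. Across all genes, a likeness of T567A to ezrin loss would raise the correlation of T567A minus wild type with empty vector minus T567D. This correlation was 0.033, which argues against a broad likeness but does not test one limited to some genes. Cholesterol enzymes, for example, were lower in wild type than in the empty-vector line and higher in T567A than in wild type. Both changes use the same wild-type libraries, so a trait of the wild-type line alone would give this pattern. Most of these enzymes were also higher in T567A than in the empty-vector line. What stays open is whether the residue, the single line or the handling of its libraries may account for the many calls.

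In the empty-vector line, 33 genes with at least 10 CPM in parental cells were called lower by over 3 on the log2 scale. Of these, 11, such as Igfbp4, Fmnl1, Itga11 and Megf6, were called higher than in the empty-vector line in all 3 ezrin lines. Parental cells mixed into the ezrin cultures would restore each gene by a like share of its parental level. In T567A the share had a 10th percentile of -0.591%, a median of 1.3% and a 90th percentile of 24.2%, and Mmp2 regained 0.123%. The empty-vector libraries common to both comparisons are argued against as the whole cause, since with genes picked by 1 of them and tested against the other 20.6% or more were still called higher in all 3 lines. By line, 18 of the 33 were called higher in wild type, 14 in T567A and 18 in T567D. In the other direction, of 16 genes far above parental in the empty-vector line, 2 were called lower in wild type, 4 in T567A and 3 in T567D, and 2 in all 3. The 2 directions were not compared by a test. The share of other tested or equally low genes called higher was not computed as a reference. Genes this low in the empty-vector line can hardly be called lower still. What stays open, untested, is whether a peculiarity of the single empty-vector line accounts for the set. That line did stand apart elsewhere, with Cdc20b at 33.9 CPM against at most 0.0584 in any other line. Each ezrin line also differed from it in the same direction on chromosomes 13 and 19. Partial restoration by ezrin may explain the set, as a hypothesis that a second empty-vector line would test.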
